A study of Drosophila melanogaster with 12 samples.

How the data were processed

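RNA from heads of unmated adult Oregon-R male flies was measured on 12 spotted cDNA arrays with 2 colours, in 3 groups of 4 arrays. Per the series' design text, males aged 3 to 4 days were kept for 7 days on food with 8 mg/ml pentylenetetrazole (PTZ), a convulsant, and then handled in 1 of 3 ways. They were moved for 3 days to food with 3.48 mg/ml ethosuximide (ETH), an antiepileptic drug, and harvested on day 10; or moved to ETH for 3 days and then to normal food for 4 days and harvested on day 14; or moved to normal food for 7 days and harvested on day 14. The other channel of each array held RNA from heads of control flies of a parallel set kept on normal food, called untreated here. Per the design text, the 4 arrays of a group are 4 biological replicates, each with its own treated and untreated pool. The p-values of the model as designed rest on a spread between such pools that was shared over all 12 arrays, after a term for the dye. They do not measure the spread of 1 group alone. In each group, replicates 1 and 2 had the treated RNA in Cy5, and replicates 3 and 4 were dye swaps with the treated RNA in Cy3, per the labels. The labels do not say whether untreated pools were shared between groups.

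Per the series' design text, the authors quantified spots in GenePix Pro 6.0, normalized ratios in Acuity 4.0, ignored spots under 100 intensity units and under a multiple of 2 of the average background during normalization, and filtered spots on saturation, quality marks and uniformity; the design text used here ends within this list. The deposited values are log2 ratios of the channels: as linear ratios, 100% of the 123 lowest values were whole multiples of 0.001 (tolerance 0.05 of a step). The scale was therefore taken from the values. The deposited medians per array ranged from -0.62 to 0.03 log2, so the arrays were not centred on 0, and the reason stays unknown. Which channel is the numerator on the dye swaps also stays unknown: no source used here states it. The deposited ratio was read as Cy5 over Cy3, and dye swaps were turned in sign. This direction is an assumption. Cy5 is channel 1 on every array in the labels, and the design text describes the swaps as part of the design. Neither says whether the swap ratios were deposited already turned, and the data do not settle it. The counts of probes and lists past the threshold without turning are given beside each comparison. Values per gene are for the turned reading unless said otherwise.

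The 27648 spots of an array were read as 13824 probes of 2 adjacent spots, which were averaged. The platform annotation used here gave 1 gene to 7558 probes, several genes to 51 and none to 6215; 7447 of the 7558 were matched by gene ID to a current symbol. No gene was named from a probe with several genes, and probes without a listed gene are called unnamed here. At the software ceiling of 16.61 log2, 5 spot values were set to missing. Each array was centred on the median of its measured probes. Between 5077 and 10433 probes had a value on an array, and 2145 had one on all 12. The number of arrays limits the precision. No pair of arrays was a duplicate: at most 0.124% of values were identical in any of the 66 pairs.

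A linear model with a mean per group and 1 dye term per probe, common to the groups, was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. A probe was tested in a group if at least 3 arrays had a value. Each group mean was tested against 0, and the differences between the day-14 groups and between day 14 and day 10 of the ETH arm were tested as contrasts. Tests were 2-sided with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Gene lists were tested with limma's cameraPR with a preset inter-gene correlation of 0.01, using 1 probe per gene (the probe with most values) and lists of at least 5 measured genes out of 33 lists, with adjustment over lists within a comparison. An estimated correlation was the alternative. That estimate was first taken from probes measured on all 12 arrays, which gave no value for several lists, and was then replaced, after this was seen, by one from all pairs of probes on the arrays they share. The model, the lists, the alternatives in the fixed set and the rule for naming genes were chosen before the data were examined.

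The rule named, per comparison, up to 12 probes in each direction past the threshold with 1 gene and the same sign on every array with a value (the sign was not asked for in differences between groups), or, where none passed, the 6 with the smallest p in each direction as not passing; up to 4 members of a list were named by smallest p, and the GABA-gated and calcium channel lists were always reported. The script was tested on simulated data made from the real spread, with 200 probes changed. For changes of 1 log2 it recovered 68.7% at day 10, 91.0% at day 14 after ETH, 88.1% at day 14 without ETH, 80.6% for the difference of the arms and 79.1% for day 14 minus day 10; for changes of 0.5 log2 the shares were 26.9%, 43.3%, 44.8%, 19.4% and 14.9%. Of the simulated calls 3.17% to 9.56% were unchanged probes. The simulated noise was independent between probes and arrays, with 1 spread per probe for all 12 arrays. It held no effect of slide position, no wider spread at day 10 and no pairing of arrays. On the real arrays, probes next to each other in a row correlated at 0.30 to 0.62. These shares therefore test the script and need not hold for the real arrays.

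Same-numbered arrays of the day-14 arms correlated at 0.20 to 0.56 in deviations from the group means, and at 0.12 to 0.31 after the dye term, in all 4 pairs over 0.1. The numbers were therefore taken to pair these arms, from the data and not from the labels. This reading was made after the fits had been run, and it is not clear-cut. Replicate 4 after ETH correlated at 0.42 with replicate 3 of the other arm, and at 0.25 after the dye term. With its own number it stood at 0.32 and 0.14. Replicate number also holds dye orientation. Alternatives were other centring and scaling, other dye terms, other filters on missing values, dye swaps not turned, the replicate number as a block, robust and weighted fits, fits on fewer arrays, averaging of probes and leaving out each array. Values corrected for position on the slide were added after seeing the data, because deposited ratios followed the print position. For these, the median of the position within a print block and the median of neighbours in a window of 11 rows and 5 columns of probes (at least 10 neighbours) were subtracted on each array. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.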

Results

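Expression in fly heads was compared between drug-treated and untreated males on 4 arrays per group: at day 10, at the end of ETH that followed PTZ; at day 14, after 4 further days on normal food; and at day 14 in flies that went from PTZ to normal food. The series title states its interest as expression change secondary to ETH during withdrawal from PTZ. The arrays gave values for 9106 to 10433 probes at day 10, 5077 to 7399 at day 14 after ETH and 6869 to 7433 at day 14 without ETH. In the order of replicates 1 to 4, the deposited median log2 ratios were -0.11, -0.06, -0.62 and -0.17 at day 10; -0.18, -0.36, 0.03 and -0.17 at day 14 after ETH; and -0.07, -0.32, -0.13 and -0.03 at day 14 without ETH. Ratios below are treated over untreated with the array median at 0. Their sign on the dye swaps rests on the assumed reading of the ratios as Cy5 over Cy3. The sign and size of each group mean, and whether it passes, rest on that reading too.

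Ratios followed position on the slide. The standard deviation of the 48 print-block medians was 0.22 to 0.37 log2 on the day-10 arrays, 0.06 to 0.21 at day 14 after ETH and 0.07 to 0.14 at day 14 without ETH. As deposited, day-10 arrays of opposite dye orientation correlated across probes at 0.38 to 0.48, which becomes negative once dye swaps are turned; after position correction the range was 0.08 to 0.16. Arrays of the same orientation correlated at 0.43 and 0.55, and at 0.21 and 0.28 after correction. Probes are not independent replicates in these correlations.

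**Figure D1:**
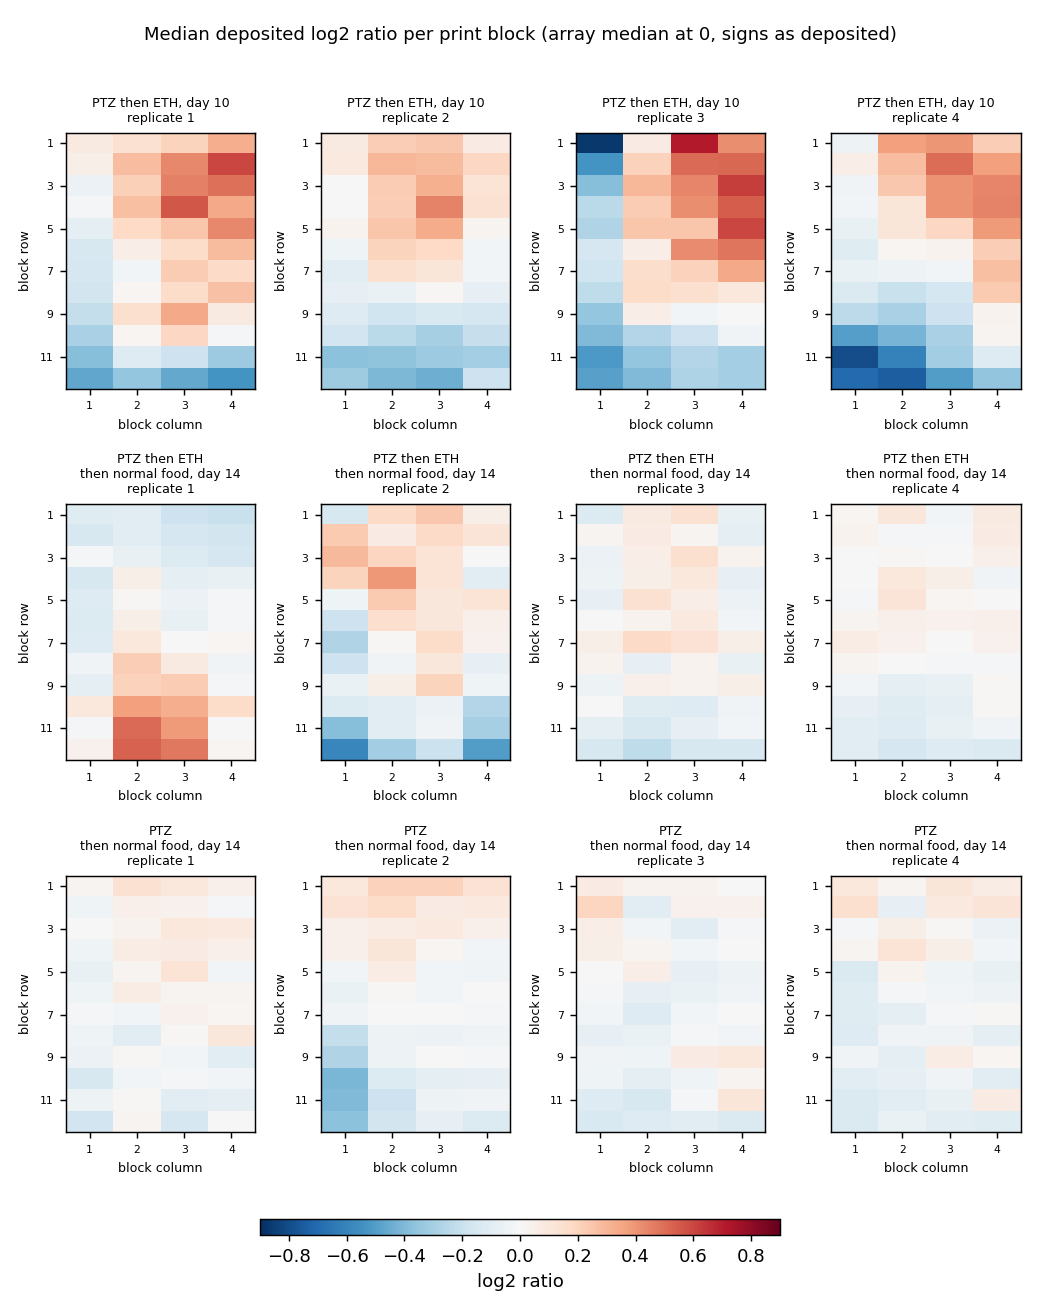
Median deposited log2 ratio in each of the 48 print blocks (12 block rows by 4 block columns) of each of the 12 arrays, with the array median at 0 and signs as deposited. The standard deviation of block medians was 0.22 to 0.37 on the day-10 arrays, 0.06 to 0.21 at day 14 after ETH and 0.07 to 0.14 at day 14 without ETH.

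At day 10, the cytochrome P450 gene Cyp6a8 (CG10248) rose by 1.90 log2 (SE 0.16, n = 4 arrays, limma adjusted p = 0.00934) and the juvenile hormone epoxide hydrolase gene Jheh2 (CG15102) rose by 0.94 (SE 0.14, n = 4, limma adjusted p = 0.0158). The mitochondrial P450 gene Cyp12d1-d rose by 0.88 (SE 0.14 from the shared fit, against a plain SD of 0.54 over its 4 day-10 arrays). CG9360 rose by 1.14 (SE 0.12, limma adjusted p = 0.00205), and CG6908, CG7382, CG2065 and CG9445 rose by 1.21, 1.10, 0.89 and 0.79. The P450 gene Cyp313a1 fell by 1.33 (SE 0.16, n = 3, limma adjusted p = 0.00462) and the odorant-binding protein gene Obp99b fell by 1.31 (SE 0.13, n = 3, limma adjusted p = 0.00462). CG14402 passed at -1.69 (SE 0.17), but it had values on 3 arrays in all, 2 with treated RNA in Cy5 and 1 dye swap at -2.82; their plain mean was -1.32 (SD 1.30, n = 3), and 1 residual degree of freedom was left. It passed in the opposite direction with dye swaps not turned, at 1.12 (adjusted p = 0.00676), and with position correction as well at 1.00 (adjusted p = 0.0415). Cyp6a8 had no day-14 values, which left 2 degrees of freedom. CG4477 fell by 0.89 (SE 0.13), and Jhbp14 and Jhbp13, of a family of juvenile hormone binding proteins, fell by 0.88 (SE 0.16) and 0.76 (SE 0.12); Jhbp13 did not pass after position correction (adjusted p = 0.0792). Jheh2 at -0.28 (adjusted p = 0.452), CG7382 at -0.0549 and Jhbp13 at 0.11 also had the opposite sign with dye swaps not turned, where CG14402 alone of the 14 named genes passed. The named genes that kept their sign were all smaller there. Cyp6a8 stood at 0.39 (limma adjusted p = 0.0931), CG9360 at 0.11 (0.811), Cyp313a1 at -0.07 (0.832) and Obp99b at -0.29 (0.491), and CG6908 was largest at 0.65 (0.133). Of 28 alternatives Cyp12d1-d passed in 8, CG2065 in 9, CG9445 in 10 and Jhbp13 in 13; of 27, Jhbp14 passed in 5 and CG4477 in 16. Other probes of the same genes gave 0.78 for Jheh2 (adjusted p = 0.0738), 0.70 for Cyp6a8 (adjusted p = 0.593), -0.71 for Obp99b (adjusted p = 0.251), 0.23 for CG7382 (adjusted p = 0.591) and -0.03 for Jhbp14 (adjusted p = 0.982), none past the threshold.

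**Figure D2:**
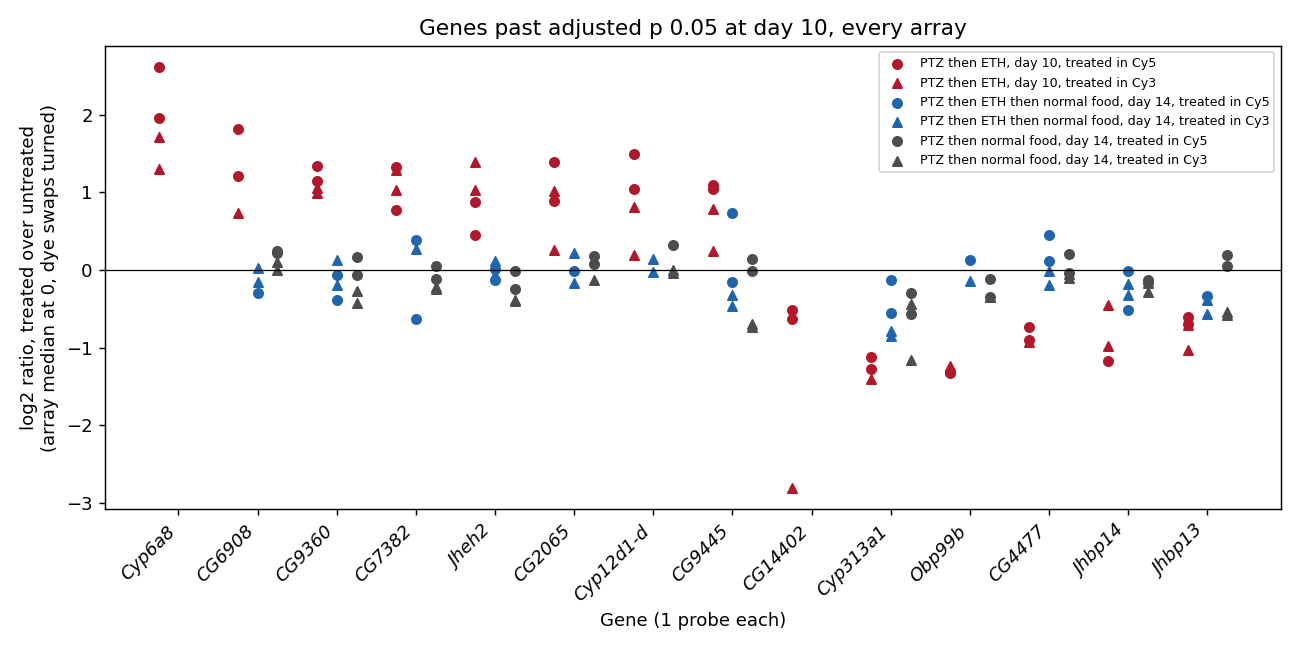
Turned log2 ratio (vertical axis) of the 14 named genes past the threshold at day 10 on every array with a value; colours mark the groups and shapes the dye that carried the treated RNA. Cyp6a8 lies between 1.30 and 2.62 on the 4 day-10 arrays, and CG9360 between 0.99 and 1.34.

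In all, 12 probes rose and 9 fell among 9479 tested by limma at day 10, and 791 had an unadjusted p under 0.05, against 474 if no probe had changed. That count was 328 with arrays scaled to a common spread, 471 without a dye term, 482 with array weights, 598 with the day-10 arrays alone, 1265 without centring and 4135 with dye swaps not turned. The 791 and the calls rest on a spread shared with the day-14 arrays. Their SD over probes was 0.27 to 0.39, against 0.46 to 0.58 at day 10, so the day-10 p-values may be too small. Of the 21, 14 carry 1 gene each, 8 higher and 6 lower. As deposited without centring, where the median of all probes stood at 0.17 against 0.02 after centring, 14 were higher and 4 lower. Position correction gave 13 higher and 11 lower, 17 of them shared with the 21. The count was 0 with arrays scaled to a common spread, 1 with the day-10 arrays alone, and 3 or 7 without replicate 2 or 4 of day 10. With dye swaps not turned it was 1771 higher and 1117 lower, sharing 1 probe with the 21, so the day-10 genes depend on the reading of the dye swaps. With position correction as well, the unturned count was 86 higher and 48 lower, so most of those calls were lost once slide position was corrected.

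The glia list was the only one of 32 lists past the threshold at day 10. Of its 14 measured genes 13 were below 0, with a median of -0.21 (cameraPR adjusted p = 0.00180; 0.0195 as adjusted p with an estimated correlation, by an estimator chosen after the first one gave this list no value). Gs2, a glutamine synthetase gene, stood at -0.37 (SE 0.13), the astrocyte gene alrm at -0.39 (SE 0.15), the innexin gene Inx2 at -0.36 (SE 0.12) and Miox, a myo-inositol oxygenase gene, at -0.37 (SE 0.14). No member passed alone, over all probes or adjusted over the list alone, where these genes had adjusted p = 0.0719. After position correction the median was -0.11 with 3 of 14 genes above 0; the adjusted p was 0.0500 with the preset correlation and 0.0894 with an estimated correlation. With dye swaps not turned the median was -0.05 (adjusted p = 0.995), and without replicate 1 of day 10 it was -0.14 (adjusted p = 0.450). The list also missed the threshold with array weights, at -0.17 (adjusted p = 0.0571), and without replicate 3 of day 10, at -0.20 (adjusted p = 0.0686).

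**Figure D3:**
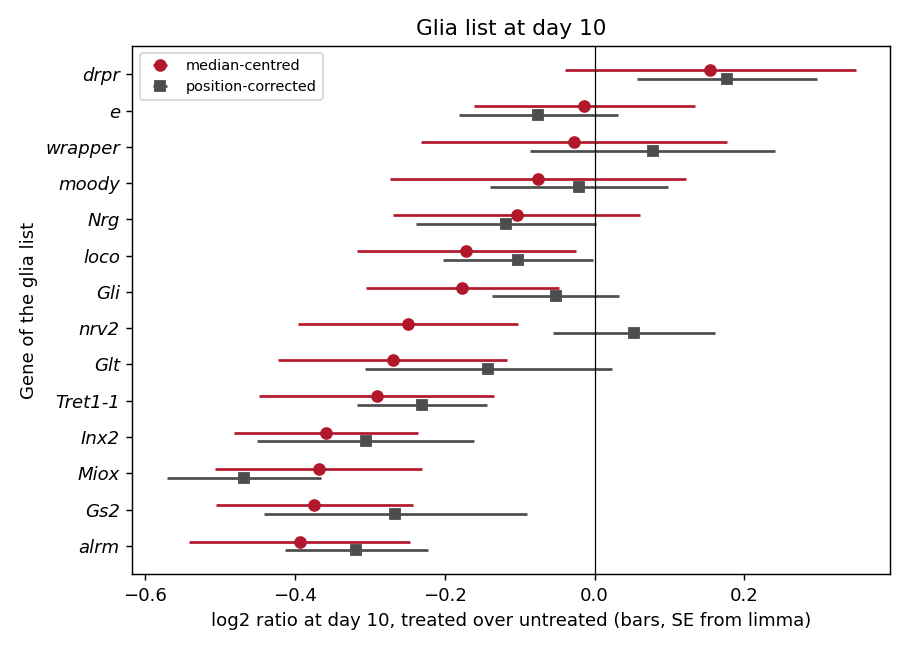
Day-10 log2 ratio (horizontal axis, bars are limma standard errors, 4 arrays or fewer) of the 14 measured genes of the glia list, from centred values and after position correction. The gene alrm is lowest at -0.39 from centred values, and drpr is highest at 0.15.

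Among 44 measured P450 genes 26 were above 0 at day 10, with no shift of the list (adjusted p = 0.751), and 20 with dye swaps not turned (adjusted p = 0.906); 2 rose and 1 fell over all probes, and 5 were higher and 2 lower adjusted over the list alone, with Cyp6a20 at 0.53 (SE 0.12) among them. With 1 probe per gene, the one with most values, 13 of the 14 named genes counted as past the threshold. P450 genes made up 3 of these 13 against 44 of 5560 tested (1-sided Fisher's exact test p = 0.000125, adjusted p = 0.00400), in mixed directions. It passed in 6 of 28 alternatives: no centring, 2 or all 4 arrays required, a robust or weighted fit, and without replicate 3 of day 10. It did not pass without any other single array, without a dye term (adjusted p = 0.623), with a dye term per group (0.0681), with the replicate block (0.960), with probes of a gene averaged (0.126), with the day-10 arrays alone (0.253), with arrays scaled to a common spread, where no gene passed, after position correction (0.0805) or local correction only (0.265); with dye swaps not turned the share was 10 of 1765, below that of all genes tested (adjusted p = 1.00). Glutathione S-transferases, which conjugate foreign compounds, had 11 of 16 genes above 0 and a median of 0.14 (adjusted p = 0.164), or 7 of 16 and -0.11 with dye swaps not turned (adjusted p = 0.995); none passed over all probes and 1, GstE3 at 0.58 (SE 0.13), adjusted over the list alone. The fat body and yolk list stood at -0.05 (adjusted p = 0.164), or 0.13 with dye swaps not turned, with 1 gene, the larval serum protein gene Lsp2 at -0.72 (SE 0.14), lower adjusted over the list alone. The actin and tubulin list stood at -0.17 (adjusted p = 0.164), or 0.0739 with dye swaps not turned, with alphaTub85E at -0.84 (SE 0.19) and Act88F at -0.32 (SE 0.11) lower adjusted over the list alone. Odorant-binding and chemosensory genes showed no shift (adjusted p = 0.963), with 2 higher and 3 lower adjusted over the list alone, Obp56e at 0.67 and Obp57c at -0.61 among them. Of the biogenic amine genes 2 were lower adjusted over the list alone, the tyrosine hydroxylase gene ple at -0.60 (SE 0.16) and the tyramine receptor gene TyrR at -0.79 (SE 0.21). Over all lists 8 genes were higher and 12 lower adjusted over the list alone, and 87 and 53 with dye swaps not turned.

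The receptors and channels that PTZ and ETH act on were measured only in part, and none of those measured passed the threshold at day 10. Of 12 listed chloride channel genes 4 were tested, and of 11 genes on the calcium channel list 6. Of GABA-gated and related chloride channels 4 genes were measured, too few for a list test: CG6927 at 0.24 (SE 0.12), alka at -0.24 (SE 0.14), Lcch3 at -0.25 (SE 0.25) and GluClalpha at 0.01 (SE 0.12). No probe annotated to the GABA receptor subunit Rdl was available here. The 6 tested genes of the calcium channel list had a median of 0.07 (adjusted p = 0.820), with unc80 at 0.21 (SE 0.13) and Ca-beta at 0.16 (SE 0.14). The list as fixed also held na, unc79 and unc80, which belong to another channel. Its median is therefore not one of calcium channel genes alone. The 5 genes of GABA synthesis, transport and GABA-B receptors had a median of -0.28 (adjusted p = 0.284), with the GABA transporter gene Gat at -0.48 (SE 0.17) and the glutamate decarboxylase gene Gad1 at 0.14 (SE 0.11). The medians of the calcium channel and GABA lists were -0.0222 and 0.0401 with dye swaps not turned. After position correction, added after seeing the data, the GABA list passed at -0.33 with 0 of 5 genes above 0 (cameraPR adjusted p = 0.0195), so Gad1 turned in sign there. That call was lost with an estimated correlation and with dye swaps not turned. No gene of these lists passed adjusted over the list alone with dye swaps turned.

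At day 14, after ETH and 4 days on normal food, no gene passed the test. The genes with the smallest p were CG9689 at -0.58 (SE 0.12, n = 4, limma adjusted p = 0.995) and Cyp313a1 at -0.58 (SE 0.12, limma adjusted p = 0.998). GXIVsPLA2, a phospholipase gene, stood at -0.49, Msr-110 at -0.43, regucalcin at -0.40 and fbp, a gluconeogenic enzyme gene, at -0.44. On the positive side were beat-IIa at 0.52, betaNACtes6 at 0.55, CG6425 at 0.57, CG17300 at 0.50, vig at 0.43 and CG31782 at 0.40. Limma called 0 of 5135 probes, with 226 at an unadjusted p under 0.05 against 257 if no probe had changed; the 226 became 128 without a dye term, 485 with arrays scaled to a common spread, 578 with only the day-14 arrays and 751 with dye swaps not turned. With dye swaps not turned it called 13 higher and 4 lower, and 6 of the 12 genes named here had the opposite sign. No list of 27 passed (lowest adjusted p = 0.121), and 2 did with dye swaps not turned, the respiratory chain list at 0.16 and cytosolic ribosomal proteins at 0.13; the P450 list had 11 of 31 genes above 0 and a median of -0.07, with 1, Cyp313a1, lower adjusted over the list alone, and cuticle genes 14 of 22 and a median of 0.08. Without turning the dye swaps these were 20 of 31 and 0.0461 (adjusted p = 0.345), and 13 of 22 and 0.0794 (adjusted p = 0.210), and over all lists 14 genes were higher and 4 lower adjusted over the list alone.

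At day 14 after PTZ and normal food, without ETH, no gene passed the test either, with the shared spread of the model as designed. Cyp313a1 stood at -0.62 (SE 0.13, n = 4, limma adjusted p = 0.449), fbp at -0.52 (SE 0.12) and colt, the gene of a mitochondrial carnitine carrier, at -0.59 (SE 0.14). BomT3, an immune peptide gene, stood at -0.48, CG7920 at -0.47 and CG12204 at -0.45. Osi6 stood at 0.60 (SE 0.13), CG11912 at 0.69 (SE 0.16), the sorting nexin gene Snx1 at 0.43, CG12081 at 0.38, Son at 0.36 and CG10710 at 0.34. Limma called 0 of 6386 probes, with 427 at an unadjusted p under 0.05 against 319 if no probe had changed (lowest adjusted p = 0.127); the 427 became 242 without a dye term and 1418 with these 4 arrays alone. The count of calls was not stable: 68 were higher and 207 lower in a fit of these 4 arrays alone, 15 and 52 with arrays scaled to a common spread, 28 and 94 with array weights, and 13 and 0 with dye swaps not turned. The first 3 of these fits gave 1, 0 and 11 calls at day 10, fewer than here. The shared spread held the day-10 arrays, whose SD over probes was 0.46 to 0.58, against 0.27 to 0.29 in this group. Calls at day 10 beside none here therefore depend on sharing that spread. No list of 26 passed (lowest adjusted p = 0.0766), and 3 did with dye swaps not turned, glycolysis at 0.16, the respiratory chain list at 0.07 and cytosolic ribosomal proteins at 0.18; glycolysis genes had a median of -0.16, with Pgi at -0.47 (SE 0.12) and Tpi at -0.32 (SE 0.10) lower adjusted over the list alone. Over all lists 5 genes were lower and none higher adjusted over the list alone, with Miox of the glia list at -0.50 (SE 0.13) among them. Without turning the dye swaps 13 were higher and none lower, and 7 of the 12 genes named here had the opposite sign.

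The arms that did and did not receive ETH were compared directly at day 14, and no gene passed the test. The difference, ETH arm minus the other, was 0.54 for the pyrimidine synthesis gene r-l (SE 0.14, n = 4 against 4, limma adjusted p = 1.00) and -1.99 for Obp19c (SE 0.63), of which another probe stood at -0.04 (SE 0.20). The genes shv at 0.65, Plekhm1 at 0.58, Sodh1 at 0.58, CG6067 at 0.51 and CG44014 at 0.40 were next on the positive side. The chaperone gene Cnx99A at -0.60 (another probe at 0.03), Cyp4ad1 at -0.46, ATPsynE at -0.43, CG6638 at -0.40 and CG14853 at -0.34 were next on the negative side. Limma called 0 of 4766 probes, with 78 at an unadjusted p under 0.05 against 238 if no probe had differed, and 0 with dye swaps not turned. The 78 became 27 without centring, 131 with dye swaps not turned, 239 with only the day-14 arrays and 275 with arrays scaled to a common spread. As 78 lies far below 238, the p-values of this contrast may be too large. Their spread was shared with the wider day-10 arrays, and the model as designed held no pairing of the arms. The 0 calls are therefore weak evidence that the arms did not differ. With the replicate number as a block, 0 passed from all 12 arrays and 1 from the day-14 arrays: Obp19c at -1.82 (SE 0.24, limma adjusted p = 0.0235), which had both values in 2 of the 4 pairs. No list of 26 passed (lowest adjusted p = 0.862), nor with dye swaps not turned. No gene passed adjusted over the list alone, and 1 was higher with dye swaps not turned, where 7 of the 12 genes named here had the opposite sign.

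Within the ETH arm, the response of CG9360 differed between days: the day-14 ratio minus the day-10 ratio was -1.27 (SE 0.17, limma adjusted p = 0.00518), from a mean of 1.14 at day 10 (SD 0.15, n = 4) to -0.13 at day 14 (SD 0.22, n = 4). One unnamed probe differed by -1.20 (adjusted p = 0.00518). Next by p, and not passing, were CG4477 at 0.98 (SE 0.16, limma adjusted p = 0.0535), the P450 genes Cyp4e2 at -1.01 (SE 0.18) and Cyp6a20 at -0.86 (SE 0.16), both with limma adjusted p = 0.0658, CG6908 at -1.32 (SE 0.24) and the probes of Jheh2 at -1.07 (SE 0.20) and -0.95 (SE 0.18). Limma called 2 of 4451 probes, both lower, with 257 at an unadjusted p under 0.05 against 223 if no probe had differed; the 257 became 128 of 2348 probes with all 4 arrays required, 171 with the arrays of these groups alone, 433 with a dye term per group, 643 without centring and 1231 with dye swaps not turned. After position correction, which was added after seeing the data, the count was 2 higher and 7 lower, both probes included; Jheh2 (adjusted p = 0.00168), CG4477, CG7382, CG9445 (each 0.00910) and CG6908 (0.0106) passed there as well. The count was 181 higher and 249 lower with dye swaps not turned, neither included. As deposited without centring, where the median of all probes stood at -0.26 against -0.01, it was 11, all lower. It was 0 without replicate 1, 2 or 4 of the day-14 ETH arm. No list of 26 passed (lowest adjusted p = 0.222), nor with dye swaps not turned, and 5 genes were higher and 5 lower adjusted over the list alone (14 and 12 with dye swaps not turned).

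Of the 21 probes past the threshold at day 10, 17 were tested at day 14 after ETH: 9 had the same sign, and their median in the day-10 direction was 0.02 against 0.94 at day 10, a value raised by having chosen the probes there. Without ETH 19 were tested at day 14 and 14 had the same sign, with a median of 0.06. With dye swaps not turned 10 of 17 and 10 of 19 had the same sign. Cyp313a1 at -0.58, Jhbp13 at -0.36 and Jhbp14 at -0.26 were among those of the same sign after ETH. Cyp6a8 and CG14402 could be tested in neither day-14 group, nor Obp99b and Cyp12d1-d after ETH. Across probes, the group effects correlated at 0.45 (Pearson; Spearman 0.45) between the day-14 groups, at 0.14 (Spearman 0.18) between day 10 and day 14 after ETH and at 0.19 (Spearman 0.22) between day 10 and day 14 without ETH. With dye swaps not turned the Pearson values were 0.54, 0.14 and 0.28. Computed between arrays of opposite dye orientation, these correlations were -0.06 and -0.15, -0.08 and -0.02, and -0.11 and -0.11, in the same order. Between arrays of the same orientation they were 0.30 and 0.65, -0.04 and 0.32, and 0.20 and 0.28. Part of any such correlation may come from untreated pools, if groups shared them.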

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

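Of the tests below, those of slide position by corrected values, of the direction of the dye swaps, of the day-10 genes at day 14, the comparison of splits by pairs, and the counts of channel assignments at day 10 and at day 14 without ETH were chosen after the result was seen; the tests on neighbouring probes and the remaining counts of splits were written first.

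The Cnx99A probe stood at 0.73 on replicate 2 of day 14 without ETH, against 0.09 to 0.15 on the other 3 arrays. The spread of print-block medians was 0.136 on that same array against 0.0693 to 0.0764 on the other 3. Of 58 groups of 4 values tested this way 2 stood out, and chance gives 2.90. Between day 10 and day 14 of the ETH arm, CG9360 differed by -1.27 and unnamed probe_5624 by -1.20, by the contrast of the limma model. Of the 35 splits of these 8 arrays, 2 gave at least the real 2 calls, the real split included, so chance is not excluded for this count. The other gave 266 and put the day-10 arrays with treated RNA in Cy5 together with the dye swaps of day 14. In turned values this is the difference between the days with dye swaps not turned, so it falls under the open reading of the swaps. The split by dye orientation itself gave 0. At day 14, the difference of the arms had 0 calls. Any split reaches a count of 0, so the 35 of 35 splits that did so show nothing. The split by dye orientation gave 812, and as it sets turned swaps against the other arrays, it falls under the same open reading of the swaps. That split keeps every same-numbered pair together; the 8 splits that part all 4 pairs, as the real one does, gave 0 each, and those that part 2 pairs gave at most 1. At day 14 after ETH and without ETH, 8 of 8 channel assignments gave as many calls as the real 0, with a highest other of 0. Any assignment reaches a count of 0, so this comparison shows nothing, and 8 assignments are also too few for a share under 0.05.

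The 21 probes past the threshold at day 10 were set against position on the slide, which argues against position as the whole source: 17 of the 20 with a corrected value stayed past the threshold, and the 18 neighbours of the probes had a median of -0.0777 (SE 0.06) in the direction of the call, against 0.94 for the probes. Cyp313a1 had no corrected value, so the check by corrected values did not cover it. Whether dye swaps were deposited already turned stays open. Probes beyond 0.5 log2 on all 4 arrays changed sign with dye orientation more often than other mixed patterns in corrected values (7 against 4 in 6 other patterns; exact binomial adjusted p = 0.00188), yet 4 of 8 such tests passed, the range of adjusted p was 0.00188 to 0.817, and probes with 1 sign on all arrays were more numerous in 6 of 8. This cannot be told apart, because a gene-specific dye bias in already turned ratios would change sign with orientation too, as a treatment effect does in unturned ones. Exchanging the channels in 8 ways gave 21 calls for the real assignment and at most 604 for another, the one that leaves the day-10 swaps unturned, with 2 of 8 giving at least 21; 8 are too few for a share under 0.05.

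As a set, the day-10 genes stood near 0 at day 14 after ETH, with Cyp313a1 at -0.58 (SE 0.12) and Jhbp13 at -0.36 (SE 0.13), neither passing, as exceptions; Cyp6a8, CG14402, Obp99b and Cyp12d1-d were not tested. Missing probes at day 14 are argued against as the whole source, since 17 of 21 were tested there with a median of 0.0151 (SE 0.06) in the day-10 direction. A wider spread at day 14 is argued against too, as it would leave the effects in place. It was hardly in question, because the SD over all probes of an array was 0.27 to 0.39 at day 14 and 0.46 to 0.58 at day 10. The day-10 calls themselves rest on the shared spread, with 1 call from the day-10 arrays alone and 0 with arrays scaled to a common spread. The 0.94 of day 10 is too high a standard, because the probes were chosen there and some fall is expected in any other group; probes chosen without 1 day-10 array had medians of 0.45, 1.34, 0.64 and 1.06 on the array left out (replicates 1 to 4; 21, 3, 14 and 5 values), and the day-14 median lay far below the lowest of these. Over the 9 of these probes with all 8 values, the median SD between arrays of one orientation at day 14 against day 10 was 0.136 against 0.141 for treated RNA in Cy5, 0.119 against 0.228 for swaps and 0.229 against 0.208 for both, and 0.188 against 0.222 for both over 2348 probes. A smaller response after ETH ended may account for the part of the fall beyond this choice of probes. This is a hypothesis for the turned reading of the dye swaps only. No group without ETH was harvested at day 10. The end of ETH can therefore not be told apart from time since PTZ, fly age or the set of arrays. Nor can the day-10 genes be assigned to ETH rather than PTZ. Without ETH, 19 of the 21 probes were tested at day 14, 14 with the same sign, with a median of 0.06 in the day-10 direction. The difference between the days of the ETH arm passed for CG9360, and after position correction also for Jheh2, CG4477, CG7382, CG9445 and CG6908.

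The lower glia list at day 10 may reflect position on the slide, which stays open. After correction the median moved from -0.21 to -0.11, and the adjusted p was 0.0500, just under the threshold, or 0.0894 with an estimated correlation. The 21 neighbours of the glia probes had a median of -0.088 (SE 0.06), neither clearly above nor below the midpoint to the glia median. Both outcomes leave position and a change in glial transcripts as not separable here. The list is also lost with dye swaps not turned.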

How the results depend on the processing

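The alternatives with position correction, with only the day-14 arrays (with or without a block) and with the correlation estimated from shared arrays were chosen after seeing the data, and the rest were planned; the cause was not tested unless said. Probe counts are in the order day 10, day 14 after ETH, day 14 without ETH, arms at day 14, and day 14 minus day 10, with 21, 0, 0, 0 and 2 from the model as designed; a count not given stayed within 1.5 times. Arrays scaled to a common spread gave 0 at day 10, 67 without ETH and 0 for day 14 minus day 10. Fits of only the groups compared gave 1 at day 10 and 275 without ETH, and array weights 11 and 122. No dye term gave 8 at day 10; a separate dye term per group gave 13 for day 14 minus day 10, no centring 11 and all 4 arrays required 7 (fewer probes tested). Dye swaps not turned gave 2888, 17, 13 and, for day 14 minus day 10, 430, and with position correction 134, 30, 45 and 23. Position correction gave 9 for day 14 minus day 10, local correction only 15; position correction with only the arrays compared gave 1, 4 and 82 for the 3 groups. The day-14 arrays alone gave 41 without ETH.

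The replicate number as a block in place of the dye term gave 12 probes at day 10, all among the 21, of which 19 were tested. The numbers were read as pairing the day-14 arms, with the exception of replicate 4 given above. There the block with only the day-14 arrays gave 1 probe in place of 0 and changed no other call. The numbers were not read as pairing day 10 with day 14: same-numbered arrays correlated at -0.12 to 0.38 after ETH (2 of 4 over 0.1) and -0.0288 to 0.38 without ETH (3 of 4). Over the series 8 of 12 arrays correlated best with their own number, a hint from the data only.

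Leaving out each array gave 3 to 22 probes at day 10, 0 to 0 at day 14 after ETH, 0 to 1 without ETH, 0 to 0 for the arms and 0 to 15 for day 14 minus day 10. At day 10 it was 3 without replicate 2 and 7 without replicate 4 of that group, 12 and 13 without replicates 3 and 4 of day 14 after ETH, and 11, 12, 11 and 13 without replicates 1 to 4 of day 14 without ETH, which entered by the shared spread and dye term. For day 14 minus day 10 it was 9, 15 and 10 without replicates 1, 3 and 4 of day 10 and 0 without replicates 1, 2 or 4 of day 14 after ETH. Without replicate 1 of day 10, 1 probe passed at day 14 without ETH.

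Lists past the threshold at day 10 were 1 as designed; 0 with swaps not turned (with or without position correction), array weights or the correlation from complete probes, which gave glia no estimate; and 2 with position correction, local correction only, or position correction with only the arrays compared. At day 14 after ETH the 0 became 2 with swaps not turned (3 with position correction) and 1 with position correction, local correction only, or position correction with only the arrays compared. Without ETH the 0 became 3 with swaps not turned, position correction, both, or position correction with only the arrays compared. For the arms position correction gave 1, also with only the arrays compared; for day 14 minus day 10 local correction only, and position correction with only the arrays compared, gave 1 each. Leaving out an array gave 0 to 2, 0 to 2, 0 to 1, 0 to 0 and 0 to 2 lists. These were 2 at day 10 without replicate 2 of that group and 0 without replicate 1 or 3; 2 at day 14 after ETH, and 2 for day 14 minus day 10, without replicate 2 of day 14 after ETH (1 without its replicate 4); and 1 without ETH without replicate 2 of that group.

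The glia median, -0.21, was -0.0469 with swaps not turned (adjusted p = 0.995), -0.0589 so with position correction (0.681) and -0.17 with array weights (0.0571); leaving out an array gave -0.31 to -0.14, with the call lost without replicate 1 (0.450) or replicate 3 (-0.20, 0.0686) of day 10. Its adjusted p ran from 5.4e-05 with all 4 arrays required to 0.995.

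The correlation of effects was 0.14 between day 10 and day 14 after ETH: 0.0795 with 2 of 4 arrays required, 0.21 with all 4, 0.10 with position correction and 0.0403 to 0.18 leaving out arrays. Between the day-14 groups it was 0.45: 0.54 with swaps not turned, 0.37 with position correction and 0.27 to 0.49. Between day 10 and day 14 without ETH it was 0.19: 0.12 with 2 of 4 arrays, 0.26 with all 4, 0.28 with swaps not turned, 0.13 with position correction and 0.0576 to 0.21.

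Genes named from lists are not counted here, and of these Gad1 fell below 0 at day 10 after position correction. No value of a gene named by comparison changed sign except with swaps not turned, where 24 of 51 did, or 23 of 46 with position correction. Past the threshold in either fit were CG7382 -0.0549, Jheh2 -0.28, CG14402 1.12 and Jhbp13 0.11, and with position correction as well Cyp12d1-d -0.0864, CG14402 1.00, Jhbp14 0.27 and, at day 14 after ETH, Msr-110 0.42; the other 20 and 19 passed in neither. P450 genes among those past the threshold at day 10 were 3, 10 with swaps not turned (their share then lower than expected) and 0 to 3 leaving out an array. At day 10, of 28 alternatives CG9360 passed in 23, Jheh2 in 21, CG7382 in 19, Jhbp13 in 13, CG9445 in 10, CG2065 in 9 and Cyp12d1-d in 8. Of 27, CG6908 and Obp99b passed in 21, Cyp6a8 in 20, CG4477 in 16 and Jhbp14 in 5; of 23, Cyp313a1 and CG14402 in 19, the latter in the opposite direction in 2. Spot intensity over background was not used here, so its limit on low values is not known.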

Other observations

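Unless said to be from centred values, list results in this part come from position-corrected values. These values, and the estimator behind the estimated correlations, were added after seeing the data, so the results are hypotheses. At day 14 after ETH, 20 of 21 cuticle genes were above 0, with a median of 0.05 (adjusted p = 0.0113). At day 14 without ETH, odorant-binding and chemosensory genes had 5 of 20 above 0 and a median of -0.10 (adjusted p = 0.0144), translation factors and aminoacyl-tRNA synthetases 6 of 25 and -0.11 (adjusted p = 0.00613), and cytosolic ribosomal proteins 4 of 18 and -0.08 (adjusted p = 0.00613). The ribosomal call was lost with an estimated correlation (adjusted p = 0.337 with an estimated correlation). In the direct comparison of the arms, 13 of 14 odorant-binding and chemosensory genes were higher in the ETH arm, by a median of 0.10 (adjusted p = 0.00951). At day 10, the list of GABA synthesis, transport and GABA-B receptors had 0 of 5 genes above 0 and a median of -0.33 (adjusted p = 0.0195), lost with an estimated correlation at adjusted p = 0.242. None of these lists passed from centred values in the model as designed. From centred values with replicate 2 of day 14 without ETH left out, ribosomal proteins passed in that group. Their median was -0.13 with 3 of 18 above 0 (cameraPR adjusted p = 0.0262). With dye swaps not turned, position-corrected values gave ribosomal proteins the opposite direction, with 15 of 18 above 0 and a median of 0.11 (adjusted p = 3.16e-05). The other calls were lost there: cuticle genes had 13 of 21 above 0 (adjusted p = 0.435), odorant-binding and chemosensory genes 10 of 20 without ETH (0.732) and 9 of 14 higher in the ETH arm (0.631), translation factors and synthetases 13 of 25 (0.732) and the GABA list 3 of 5 (0.336).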
